A study of Schizosaccharomyces pombe with 12 samples.

How the data were processed

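Total RNA from 4 strains of fission yeast, harvested in growing culture and extracted with hot phenol, was hybridised to Affymetrix tiling arrays after labelling with a double-stranded target assay, per the labels' protocols. There were 12 arrays, 3 biological replicates per strain per the series' design text. The deposited table holds log2 levels, 1 per annotated gene or non-coding RNA and array, already summarised from probes by the authors; the software named per the submitters' processing notes is R 2.10.0 and the affy package. Background correction, normalization, probe summary, annotation and genome build are not given in the sources used here. The scale and centring of the log2 values are therefore unknown beyond what the values show: array medians lie between 11.37 and 11.42, and the arrays are not identical in distribution. Such processing can compress changes of dim features, whose signal holds background, and shared probes can mix near-identical copies (wtf, tlh, subtelomeric and Tf2 families); target from both strands is summed, so overlapping genes are uncertain. No detection calls were used here. Each array's depth is its signal; precision is limited by 3 arrays per strain. The median SD within a strain was 0.0715 in wild type, 0.0697 in dcr1Δ, 0.0538 in dcr1ΔC33 and 0.0653 in dcr1-SHSS (log2), and no 2 arrays were closer than a median absolute difference of 0.057, so each counted as a replicate.

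Of the 5483 systematic IDs, 5357 matched the gene table of assembly ASM294v3 (5337 by locus tag and 20 by synonym), and 4252 of all took a symbol; the others keep the ID of the file. The table served only for names and for which genes neighbour each other.

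The deposited log2 levels were used as given in limma 3.58.1 under R 4.3.3: a linear model with 4 groups over all 12 arrays, empirical Bayes moderation (prior degrees of freedom 2.44, residual 8), 2-sided tests and Benjamini-Hochberg adjustment over all 5483 features, with an adjusted p threshold of 0.05 and no fold filter. Each mutant was compared with wild type and the mutants with each other, 6 comparisons in all. Values are log2 changes with their moderated SE. Named genes were chosen by a rule: dcr1; against wild type, the 10 highest and 10 lowest changes past the threshold with all 3 mutant arrays above or below all 3 wild-type arrays, a separation that chance gives in 10 percent of 3 against 3; between mutants, 5 each way; and per gene list up to 3 members with the largest change past the threshold, or otherwise the member with the smallest p.

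Of 25 gene lists 21 had at least 3 measured members and were tested with camera (preset correlation 0.01), adjusted over 63 tests; tests between mutants were adjusted separately. Lists without measured features were those of centromeric features by name and of mitochondrially encoded genes. Subtelomeric genes were taken by the clone prefix of their IDs. Cytosolic ribosomal protein genes were taken by symbol (rpl, rps or rpp and a digit) without the planned check of the product. That list therefore also holds genes such as rpp1 and rpp21, which do not encode ribosomal proteins. Long non-coding RNAs were the features annotated as lncRNA (331) or ncRNA (32). The other members of that list are IDs starting SPNCRNA that matched no reference gene. Of 63 tests, 28 passed; 0 passed with an estimated correlation, whereas fry gave 32 directional and 55 mixed calls. At unadjusted p some lists kept a low value with an estimated correlation, but no list call against wild type held after adjustment.

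The replicate numbers of the array titles were checked for pairing by the correlation of same-numbered arrays' deviations from their group means. Every pair exceeded 0.1 for dcr1Δ and wild type (0.151, 0.354 and 0.252), dcr1ΔC33 and wild type (0.177, 0.388 and 0.223), dcr1ΔC33 and dcr1Δ (0.184, 0.3 and 0.131) and dcr1-SHSS and dcr1Δ (0.178, 0.437 and 0.266), so the numbers were treated as pairing there. For dcr1-SHSS the first pair fell short with wild type (0.093, then 0.284 and 0.266) and with dcr1ΔC33 (0.021, then 0.351 and 0.139). The numbers were not treated as pairing there, although the other pairs exceeded 0.1 and dcr1-SHSS paired with dcr1Δ. A replicate effect in these comparisons is therefore not excluded. The main model has no block, so its counts, list tests and named genes leave the pairing out. The pairing entered only in an alternative fit with the replicate number as a block. That fit raised the count from 172 to 295 in dcr1Δ versus wild type and from 433 to 847 in dcr1ΔC33 versus dcr1Δ.

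The alternatives were quantile normalization, median centring, leaving out the lowest 20 percent of features (mean level up to 9.46), the arrays of the compared strains alone, moderation with an intensity trend and robust hyperparameters, the replicate block, each array left out in turn, a change of at least 1.5-fold, an adjusted p of 0.01, and for lists an estimated correlation and fry. The design, the tests, the rule for named genes, the lists and these alternatives were set before the data were examined. The centromere-gap RNAs, lying between per1 and emc5, rpb1 and yox1, and meu27 and ppc1, the 40 outermost genes per end of chromosomes I and II, and families of symbols with at least 10 members were added after seeing the data.

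The model was tested on simulated data modelled on dcr1Δ versus wild type with 5483 features: it recovered 54.4 percent of planted log2 changes of 0.25, 87.2 percent of 0.5, 95.2 percent of 1 and 100 percent of 2, with 4.8 percent false calls. For dcr1-SHSS versus wild type camera called a planted shift of 0.3 in 100 percent of 5 runs and an unchanged list in 0 percent; the simulated features were independent of each other, unlike real genes. Figures were drawn with matplotlib 3.10.9.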

Results

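RNA levels were measured on 12 tiling arrays of fission yeast, Schizosaccharomyces pombe, from 4 strains with 3 biological replicates each. The strains were wild type, dcr1Δ, which lacks the Dicer gene dcr1, dcr1ΔC33 and dcr1-SHSS. The labels give only the names of these 2 alleles. From general knowledge, not from the sources used here, the first is read as shortened at the C-terminus of Dicer and the second as changed in a zinc-binding motif of the same protein. Dicer is the ribonuclease that cuts double-stranded RNA in the RNA interference pathway, which silences the repeats at the fission yeast centromeres. The study's title concerns an extended RNA-binding domain of Dicer and its retention in the nucleus. The comparisons ask how far each allele changes the transcriptome and whether dcr1ΔC33 and dcr1-SHSS resemble the deletion. Each array gave 1 log2 level for each of 5483 features, and the array medians lay between 11.37 and 11.42. The number of arrays limits the precision. The labelled target was double-stranded, so RNA from a feature and RNA from the opposite strand are not told apart.

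The targeted gene dcr1 (SPCC188.13c) lay at log2 levels of 10.49, 10.57 and 10.60 on the wild-type arrays and at 5.52, 5.80 and 5.37 on the dcr1Δ arrays. It was at least 31.8-fold lower in dcr1Δ (log2 change -4.99 ± 0.09 SE, n = 3 per group, adjusted p = 1.15e-10). This is a lower bound, because the dcr1Δ values are among the lowest of each array and so background. On the dcr1ΔC33 arrays it lay at 10.86, 10.89 and 10.85, which was 0.31 ± 0.09 above wild type (adjusted p = 0.02; 0.0628 without wild-type array 1 and 0.058 without dcr1ΔC33 array 2). On the dcr1-SHSS arrays it lay at 10.67, 10.70 and 10.64, a difference of 0.12 ± 0.09 that did not pass the threshold (adjusted p = 0.304). The deletion strain thus carried little dcr1 signal, while the level of dcr1 RNA was not found lower in dcr1ΔC33 or dcr1-SHSS.

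**Figure D1:**
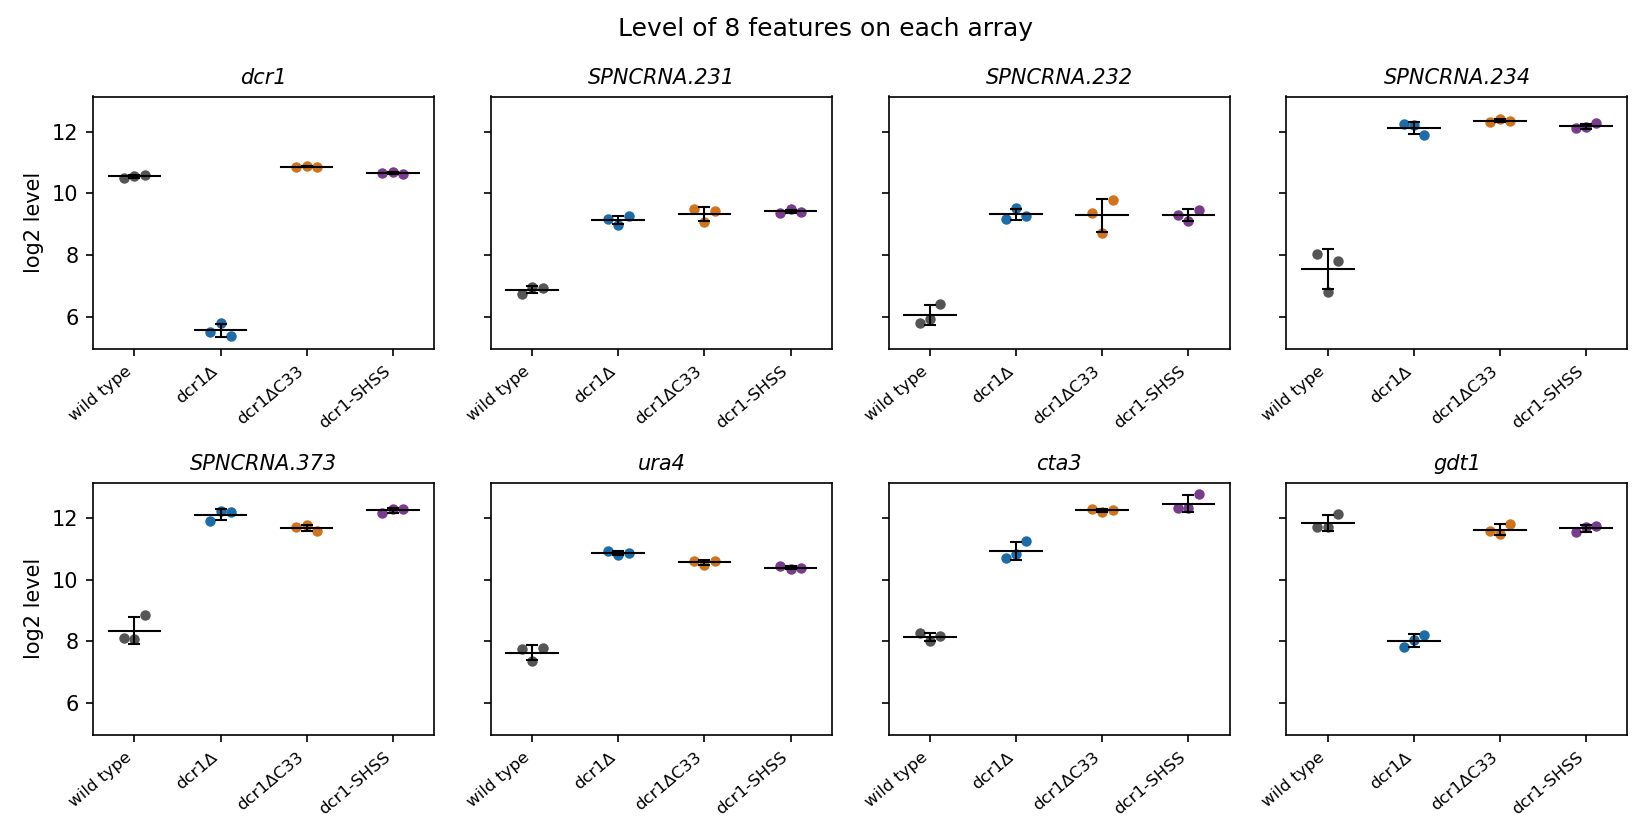
Log2 level (vertical axis) of 8 features on each of the 12 arrays, grouped by strain (horizontal axis); points are arrays, horizontal lines are the means of 3 arrays and bars are 1 SD. The dcr1 level is low on the dcr1Δ arrays alone (5.37 to 5.80), whereas SPNCRNA.234 averages 7.55 in wild type and 12.12 in dcr1Δ.

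In dcr1Δ, the 3 features that rose most against wild type were non-coding RNAs from the gene gaps that hold the centromeres. SPNCRNA.234 rose 23.8-fold (log2 change 4.57 ± 0.25 SE, n = 3 per group, adjusted p = 2.06e-06), SPNCRNA.373 rose 13.4-fold (3.75 ± 0.18) and SPNCRNA.232 rose at least 9.61-fold (3.27 ± 0.24). The value for SPNCRNA.232 is a lower bound in every mutant, because its wild-type level of 6.05 is about that of background. The marker gene ura4, which encodes an enzyme of pyrimidine synthesis, rose 9.34-fold (3.22 ± 0.10, adjusted p = 2.25e-08). Whether any of the strains carries a ura4 reporter or a different ura4 allele from the others is not given in the sources used here, so the ura4 differences may reflect strain construction. The cation-transporting ATPase gene cta3 rose 6.88-fold (2.78 ± 0.15), and SPNCRNA.231, from the same gap as SPNCRNA.234, rose 4.77-fold (2.25 ± 0.11). The subtelomeric genes pcm2 and SPAC186.02c rose by 1.87 ± 0.15 and 1.80 ± 0.18. The ferric reductase gene frp2 rose by 1.76 ± 0.06, and ecl1, a small gene named for long life in stationary phase, by 1.66 ± 0.11. Beside dcr1, the largest decrease was at gdt1 (SPAC186.05c), which was 14.0-fold lower (-3.81 ± 0.14, adjusted p = 5.69e-08).

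Other features that fell in dcr1Δ were ftm4 (-1.32 ± 0.20), SPAC186.04c (-0.97 ± 0.14), the pseudogene SPBPB10D8.03 (-0.64 ± 0.09), and the acid phosphatase gene pho1 (-0.59 ± 0.05). Smaller decreases were those of the fluoride exporter gene fex2 (-0.54 ± 0.10), the ribosomal protein gene rpl1602 (-0.32 ± 0.07), SPAC3G6.05 (-0.29 ± 0.06) and the chromatin remodelling subunit gene ssr3 (-0.25 ± 0.03). In all, 172 of 5483 features passed the threshold, 154 higher and 18 lower, and 56 of the higher and 6 of the lower moved at least 1.5-fold. Fitting the replicate number as a block raised the count to 295 (250 higher, 45 lower), and a fit to the arrays of these 2 strains alone lowered it to 73. It was 96 without wild-type array 2, 82 without dcr1Δ array 2 and 95 without dcr1Δ array 3. The calls for fex2, rpl1602 and SPAC3G6.05 were lost without some single arrays of either strain (adjusted p up to 0.0795, 0.16 and 0.0888), that of rpl1602 also with the block (0.0515). Those of SPAC186.04c and ssr3 were lost in the fit to these 2 strains alone (0.057 each). By contrast dcr1, gdt1, ftm4, pho1 and SPBPB10D8.03 passed without each array in turn.

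Of the 24 core environmental stress genes, which respond to many kinds of stress, 7 rose in dcr1Δ and none fell, or 10 and none adjusted over the list alone (camera adjusted p = 7.83e-07). The call was lost at adjusted p = 0.252 with an estimated correlation. Examples were cta3, the metallothionein gene zym1 (1.27 ± 0.14, adjusted p = 0.000448) and the sulfiredoxin gene srx1 (0.68 ± 0.15, adjusted p = 0.0422). The call for srx1 was lost without wild-type array 1 or 2 or dcr1Δ array 2 or 3 (adjusted p up to 0.16), after quantile normalization or median centring, and in the fit to these 2 strains alone (0.166). Of 472 long non-coding RNAs 31 rose and none fell, or 48 and 1 adjusted over the list alone (camera adjusted p = 5.82e-10). This became adjusted p = 0.115 with an estimated correlation, and quantile normalization also ended the call (0.144). The wtf genes, a family of spore-killing elements with closely similar copies whose probe signals are uncertain, had 4 of 24 members higher and none lower, or 8 and none adjusted over the list alone (camera adjusted p = 1.31e-05, and adjusted p = 0.115 with an estimated correlation). Their highest members past the threshold were wtf7 (0.39 ± 0.09), wtf10 (0.39 ± 0.09) and wtf20 (0.37 ± 0.09), each lost without some single arrays of either strain (adjusted p up to 0.149, 0.138 and 0.152).

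Of 120 subtelomeric genes, 9 rose and 4 fell in dcr1Δ, or 22 and 6 adjusted over the list alone (camera adjusted p = 0.00257, and adjusted p = 0.565 with an estimated correlation). The gene gdt1 was among those that fell, and leaving out the lowest 20 percent of features ended the call. The helicase genes tlh1 and tlh2 at the chromosome ends did not pass, and tlh1 differed by 1.21 ± 0.37 (adjusted p = 0.126), although 1 of the 2 passed adjusted over the list alone. Of 16 heat shock and chaperone genes, the small heat shock gene hsp16 alone passed (1.46 ± 0.19, adjusted p = 0.00196), with no shift of the list (camera adjusted p = 0.844, direction down; median -0.03 and mean 0.12). Among 24 meiosis and sporulation genes isp3 (0.91 ± 0.11) and spo6 (0.48 ± 0.07) rose, or 3 adjusted over the list alone (camera adjusted p = 0.318). Of 12 genes of the G1/S transition cdt1 rose (0.43 ± 0.07), or 3 adjusted over the list alone. The G1/S list gave camera adjusted p = 0.0111, which became adjusted p = 0.45 with an estimated correlation and 0.0538 without wild-type array 1.

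Of 4 phosphate acquisition genes pho1 alone fell, or 2 adjusted over the list alone (camera adjusted p = 0.0104, and adjusted p = 0.252 with an estimated correlation). Of 29 pseudogenes only SPBPB10D8.03 passed and fell, or 1 up and 1 down adjusted over the list alone, although the list's shift was upward (camera adjusted p = 0.00951, and adjusted p = 0.323 with an estimated correlation; 0.0639 without wild-type array 3). Of 8 iron acquisition genes none passed (camera adjusted p = 0.0409, and adjusted p = 0.617 with an estimated correlation; 0.637 without wild-type array 1 and lost without dcr1Δ array 3 too). Of 139 cytosolic ribosomal protein genes rpl1602 alone passed and none adjusted over the list alone (median log2 change -0.03, camera adjusted p = 0.0014). The list had adjusted p = 0.622 with an estimated correlation and 0.0601 without wild-type array 2. Its direction reversed, short of the threshold, after quantile normalization (0.737). Its median in dcr1Δ, -0.027, was not below that of other features at the same signal level. Among 1000 lists matched on level the medians centred on -0.03, with the lowest at -0.042. Of 25 RNA interference and heterochromatin factors only dcr1 itself fell, or 2 up and 1 down adjusted over the list alone (camera adjusted p = 0.929, direction down; median 0.03 and mean -0.17). No member passed among 3 Tf2 retrotransposons (camera adjusted p = 0.354), 13 hexose transport and glucose-repressed genes (0.167; 2 up adjusted over the list alone), 18 ribosome biogenesis genes (0.604, direction down with a mean of 0.006; with the replicate block imp3 in dcr1Δ versus wild type passes, at adjusted p = 0.0224) and 11 histone genes (0.312). Among the 11 genes of the nitrogen-responsive transport list, not all of which encode transporters, isp6 alone rose (camera adjusted p = 0.288). A single member rose among 17 mating and pheromone genes (map2, camera adjusted p = 0.97, direction down with a mean of 0.04). The 10 strain marker genes also had 1 (ura4, camera adjusted p = 0.844, direction up with a median of -0.02). The same held for 15 mitosis and cell separation genes (spo12; 0.213; 2 up adjusted over the list alone) and 9 flocculation genes (pfl9; 0.333; 3 up and 1 down adjusted over the list alone). The calls were lost for map2 without wild-type array 2 or 3 or any dcr1Δ array (adjusted p up to 0.153), for spo12 without dcr1Δ array 3 (0.0516) and for pfl9 without dcr1Δ array 2 (0.0701). The call for isp6 was lost in the fit to these 2 strains alone (0.0598). The small RNA snoR61 differed by 0.05 ± 0.04 (adjusted p = 0.589).

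In dcr1ΔC33, SPNCRNA.234 rose 28.1-fold against wild type (log2 change 4.81 ± 0.25 SE, n = 3 per group, adjusted p = 5.03e-07), cta3 17.0-fold (4.09 ± 0.15), SPNCRNA.373 10.1-fold (3.33 ± 0.18) and SPNCRNA.232 at least 9.42-fold (3.24 ± 0.24). The marker ura4 rose 7.60-fold (2.93 ± 0.10), SPAC186.02c and frp2 each by 2.89 (± 0.18 and ± 0.06), the uridine ribohydrolase gene urh1 by 2.69 ± 0.11, SPCC70.04c by 2.61 ± 0.11 and the protein kinase gene ppk31 by 2.59 ± 0.16. The largest decrease was at SPAC8C9.04, 5.30-fold lower (-2.41 ± 0.09, adjusted p = 1.17e-07). The other lowest changes were those of fex2 (-1.03 ± 0.10), the flocculin gene pfl7 (-0.95 ± 0.15), the cyclophilin gene cyp3 (-0.85 ± 0.10), SPBPB10D8.03 (-0.81 ± 0.09), smp2 (-0.68 ± 0.15), the oligosaccharyltransferase subunit gene ost4 (-0.67 ± 0.12), SPAC9.06c (-0.65 ± 0.10), rps2202 (-0.62 ± 0.12) and cbp7 (-0.62 ± 0.07). The smp2 level of 6.24 in dcr1ΔC33 is about that of background, so the size of its change is uncertain.

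In all, 1771 of 5483 features passed in dcr1ΔC33, 807 higher and 964 lower, of which 223 and 12 moved at least 1.5-fold; the lower calls were thus mostly small. The count was 1178 (602 higher, 576 lower) without dcr1ΔC33 array 3. The list counts below are to be read beside the 807 and 964 of 5483. A similar share in a list, such as the rises among RNA interference and heterochromatin factors, does not set that list apart.

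Stress genes led the lists in dcr1ΔC33. Of 24 core environmental stress genes 17 rose and none fell, or 19 and none adjusted over the list alone, among them cta3, zym1 (2.16 ± 0.14) and srx1 (1.20 ± 0.15). Here camera gave adjusted p = 2.57e-10, and adjusted p = 0.115 with an estimated correlation. Heat shock and chaperone genes rose in 5 of 16 cases with 1 lower, led by hsp16 (1.96 ± 0.19), the Hsp70 gene ssa1 (1.06 ± 0.18) and the disaggregase gene hsp104 (0.69 ± 0.10), while the list as a whole did not pass (camera adjusted p = 0.12). Of 13 hexose transport and glucose-repressed genes 4 rose, including the invertase gene inv1 (1.32 ± 0.18), the gluconeogenic gene fbp1 (1.08 ± 0.24) and the maltase gene agl1 (0.60 ± 0.10). This list gave camera adjusted p = 0.0111, and adjusted p = 0.617 with an estimated correlation. Of 8 iron acquisition genes frp1 (1.17 ± 0.28) and str2 (0.25 ± 0.04) rose (camera adjusted p = 0.0413, and adjusted p = 0.617 with an estimated correlation; up to 0.406 without wild-type array 1 or dcr1ΔC33 array 2 or 3).

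Of 120 subtelomeric genes 43 rose and 7 fell in dcr1ΔC33, or 45 and 7 adjusted over the list alone, with SPAC186.02c, pcm2 (2.45 ± 0.15) and the enolase gene eno102 (2.28 ± 0.20) highest (camera adjusted p = 2.02e-06, and adjusted p = 0.323 with an estimated correlation). Of 472 long non-coding RNAs 117 rose and 10 fell, or 110 and 9 adjusted over the list alone (camera adjusted p = 8.34e-09, and adjusted p = 0.115 with an estimated correlation; quantile normalization ended the call). Of 24 wtf genes 14 rose and none fell, or 15 and none adjusted over the list alone, such as wtf25 (0.54 ± 0.14); camera gave adjusted p = 9.25e-06, and adjusted p = 0.115 with an estimated correlation. Of 29 pseudogenes 12 rose and 2 fell, with SPCC18B5.02c (1.80 ± 0.33), SPBPB21E7.08 (1.06 ± 0.13) and SPBC18E5.15 (0.98 ± 0.18) highest (camera adjusted p = 0.00397, and adjusted p = 0.254 with an estimated correlation).

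Part of the genes of ribosome production fell in dcr1ΔC33. Of 139 cytosolic ribosomal protein genes 52 fell and 1 rose, or 54 and 1 adjusted over the list alone, with rps2202, rpl1603 (-0.51 ± 0.11) and rpl102 (-0.35 ± 0.08) lowest. For these camera gave adjusted p = 1.35e-08, and adjusted p = 0.53 with an estimated correlation. After quantile normalization 31 fell and 1 rose, beside 1175 and 692 of all 5483 features. Under that setting the share that fell was thus similar to that of all features, while the share that rose was lower. Of 18 ribosome biogenesis genes 7 fell and none rose, or 8 and 1 adjusted over the list alone, among them nop10 (-0.41 ± 0.10), nop56 (-0.28 ± 0.05) and nuc1, a subunit gene of RNA polymerase I (-0.24 ± 0.04). That list's camera adjusted p of 0.0463 became adjusted p = 0.617 with an estimated correlation, and the call was also lost under quantile normalization, median centring, without the lowest 20 percent of features and, at up to 0.122, without wild-type array 1 or dcr1ΔC33 array 2.

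Smaller groups were mixed in dcr1ΔC33. All 4 members of the phosphate acquisition list passed, with tgp1 higher (0.38 ± 0.07) and pho4 (-0.28 ± 0.05), pho1 (-0.24 ± 0.05) and pho84 lower (camera adjusted p = 0.337). Of 12 G1/S genes 4 fell, including the kinase gene mik1 (-0.42 ± 0.07) and the cyclin gene cig2 (-0.26 ± 0.04; camera adjusted p = 0.416). Of 15 mitosis and cell separation genes fkh2 (-0.15 ± 0.04) and adg3 (-0.15 ± 0.04) fell (camera adjusted p = 0.0629, and 0.0451 with the replicate block). The call for adg3 was lost without wild-type array 3 or dcr1ΔC33 array 2 or 3 (adjusted p up to 0.0599). Of 25 RNA interference and heterochromatin factors 4 rose, including dcr1 itself and cid12 (0.30 ± 0.07; adjusted p = 0.0634 after quantile normalization), and dsh1 fell (-0.36 ± 0.06; camera adjusted p = 0.819, direction up with a median of -0.01). Members passed in both directions, with no shift of the list by camera, among mating and pheromone genes (2 higher, 1 lower of 17; 0.672), meiosis and sporulation genes (3 and 2 of 24, with mei3 at 1.15 ± 0.15; 0.374), histone genes (2 and 1 of 11; 0.844), flocculation genes (1 and 2 of 9; 0.97) and strain marker genes (1 and 1 of 10; 0.599). With fry the strain markers passed upward (adjusted p = 0.0379). Signs differed among histones (direction up, median -0.02), flocculation genes (direction down, median 0.07 and mean -0.10) and strain markers (direction down, median -0.06 and mean 0.22, raised by ura4). In the nitrogen-responsive transport list 3 of 11 genes rose, with isp6 at 0.78 ± 0.06 (camera adjusted p = 0.125). No Tf2 element passed (camera adjusted p = 0.381). The gene tlh1 differed by 0.84 ± 0.37 without passing (adjusted p = 0.109) and snoR61 by 0.02 ± 0.04.

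In dcr1-SHSS, the highest features against wild type were SPNCRNA.234 (24.7-fold, log2 change 4.63 ± 0.25 SE, n = 3 per group, adjusted p = 5.51e-07), cta3 (19.9-fold, 4.31 ± 0.15), SPNCRNA.373 (14.9-fold, 3.90 ± 0.18) and SPNCRNA.232 (at least 9.45-fold, 3.24 ± 0.24). SPAC186.02c rose by 3.04 ± 0.18, frp2 by 3.00 ± 0.06, ppk31 by 2.97 ± 0.16, osr1 by 2.91 ± 0.17, pcm2 and SPCC70.04c each by 2.87 (± 0.15 and ± 0.11), and ura4 by 2.75 ± 0.10. The lowest features past the threshold were the pseudogene SPBCPT2R1.10 (-1.49 ± 0.51), pfl7 (-1.27 ± 0.15), SPBPB10D8.03 (-1.19 ± 0.09), SPAC212.04c (-1.08 ± 0.15), SPAC977.03 (-1.03 ± 0.23), the fluoride exporter gene fex1 (-0.96 ± 0.32), meu16 (-0.85 ± 0.09), thi201 (-0.75 ± 0.09), atl1 (-0.71 ± 0.08) and yar1 (-0.67 ± 0.11).

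In all, 2234 of 5483 features passed in dcr1-SHSS, 822 higher and 1412 lower, of which 251 and 18 moved at least 1.5-fold. The list counts below are to be read beside the 822 and 1412 of 5483. A similar share in a list, such as the falls among RNA interference and heterochromatin factors, does not set that list apart. The median log2 change over all features was -0.057, beside a median SE of 0.059. Median centring gave 877 higher and 1173 lower, so the number of small decreases depends in part on the centring of the arrays. The calls for SPBCPT2R1.10 (adjusted p up to 0.122 without wild-type array 1 or 2 or dcr1-SHSS array 2) and fex1 (up to 0.131 without any 1 of the wild-type arrays or dcr1-SHSS array 1 or 2) were lost without single arrays.

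Of 24 core environmental stress genes 19 rose and 1 fell in dcr1-SHSS, or 21 and 1 adjusted over the list alone, with cta3, zym1 (2.35 ± 0.14) and srx1 (1.52 ± 0.15) highest. For this list camera gave adjusted p = 6.25e-12, and adjusted p = 0.115 with an estimated correlation. Of 16 heat shock and chaperone genes 5 rose and 2 fell, or 6 and 2 adjusted over the list alone, led by hsp16 (2.16 ± 0.19), ssa1 (1.16 ± 0.18) and the mitochondrial chaperone gene hsp78 (0.79 ± 0.12). That list's camera adjusted p of 0.0463 became adjusted p = 0.631 with an estimated correlation, and the call was lost, at up to 0.209, without wild-type array 1 or dcr1-SHSS array 1 or 3. Of 13 hexose transport and glucose-repressed genes 5 rose, with inv1 (1.44 ± 0.18), fbp1 (1.36 ± 0.24) and agl1 (0.95 ± 0.10) highest (camera adjusted p = 0.00951, and adjusted p = 0.617 with an estimated correlation; 0.0801 without dcr1-SHSS array 2). Of 8 iron acquisition genes frp1 (1.14 ± 0.28), str2 (0.42 ± 0.04) and the siderophore synthesis gene sib1 (0.39 ± 0.08) rose (camera adjusted p = 0.00478, and adjusted p = 0.53 with an estimated correlation; 0.0575 without wild-type array 1).

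Of 120 subtelomeric genes 36 rose and 16 fell in dcr1-SHSS, or 38 and 18 adjusted over the list alone, with SPAC186.02c, pcm2 and cmt2 (2.61 ± 0.26) highest (camera adjusted p = 0.000356, and adjusted p = 0.53 with an estimated correlation). Of 472 long non-coding RNAs 99 rose and 36 fell, or 95 and 33 adjusted over the list alone (camera adjusted p = 0.000211, and adjusted p = 0.323 with an estimated correlation). Of 24 wtf genes 14 rose and none fell, or 16 and none adjusted over the list alone, such as wtf22 (0.71 ± 0.18) and wtf25 (0.56 ± 0.14); camera gave adjusted p = 2.86e-06, and adjusted p = 0.115 with an estimated correlation. Of 29 pseudogenes 11 rose and 5 fell, or 11 and 6 adjusted over the list alone, with SPCC18B5.02c (2.16 ± 0.33) and SPBPB21E7.08 (1.20 ± 0.13) highest (camera adjusted p = 0.0268, and adjusted p = 0.417 with an estimated correlation; up to 0.066 without wild-type array 3 or dcr1-SHSS array 2).

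Of 139 cytosolic ribosomal protein genes 79 fell and none rose in dcr1-SHSS, or 82 and none adjusted over the list alone, with rpl1603 (-0.64 ± 0.11), rps2202 (-0.60 ± 0.12) and rpp203 (-0.54 ± 0.07) lowest. For this list camera gave adjusted p = 8.34e-09, and adjusted p = 0.53 with an estimated correlation. Of 18 ribosome biogenesis genes 8 fell and none rose, including nop56 (-0.46 ± 0.05), nuc1 (-0.33 ± 0.04) and nog1 (-0.23 ± 0.06). That list's camera adjusted p of 0.0268 became adjusted p = 0.617 with an estimated correlation, and up to 0.0961 without wild-type array 1 or dcr1-SHSS array 2. Of 15 mitosis and cell separation genes 8 fell, such as the glucanase genes agn1 (-0.34 ± 0.06) and eng1 (-0.18 ± 0.05) and the checkpoint target gene slp1 (-0.23 ± 0.06; camera adjusted p = 0.0609). Of 12 G1/S genes 4 fell and 1 rose, with mik1 (-0.62 ± 0.07) and cig2 (-0.31 ± 0.04) lowest (0.381).

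With camera the other lists in dcr1-SHSS did not shift as a whole. With fry the phosphate acquisition list passed downward (adjusted p = 0.0215), and Tf2 retrotransposons (0.0274) and histones (0.0336) passed upward. All 4 members of the phosphate acquisition list passed, with tgp1 higher (0.43 ± 0.07) and pho4 (-0.33 ± 0.05), pho84 (-0.31 ± 0.08) and pho1 lower (camera adjusted p = 0.495). Of 25 RNA interference and heterochromatin factors 1 rose and 6 fell, or none and 1 adjusted over the list alone, with dsh1 at -0.29 ± 0.06 (0.855). Of 10 strain marker genes ura4 rose and 4 fell, including his5 (-0.45 ± 0.07) and ade1 (-0.22 ± 0.03; 0.337). Of 11 histone genes hht2 (0.27 ± 0.04) and hhf3 rose, or 1 adjusted over the list alone (0.337). Of 3 Tf2 retrotransposons Tf2-10 rose (0.48 ± 0.13, camera adjusted p = 0.201). In the nitrogen-responsive transport list of 11 genes isp6 (0.93 ± 0.06) and isp4 (0.53 ± 0.14) rose (camera adjusted p = 0.168). The call for hhf3 was lost without any single array of either strain (adjusted p up to 0.132). Members passed in both directions among mating and pheromone genes (1 higher, 2 lower of 17; 0.521), meiosis and sporulation genes (3 and 4 of 24, with mei3 at 1.17 ± 0.15 and mde2 at -0.38 ± 0.07; 0.792) and flocculation genes (1 and 2 of 9, with pfl8 at -0.53 ± 0.08; 0.97). Signs differed among meiosis genes (direction up, median -0.04), flocculation genes (direction up, median -0.02 and mean -0.18) and strain markers (direction down, median -0.08 and mean 0.14). Neither tlh gene passed (tlh2 at -0.41 ± 0.30, adjusted p = 0.292), nor did snoR61 (0.11 ± 0.04, adjusted p = 0.0743; 1 of 1 adjusted over the list alone).

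**Figure D2:**
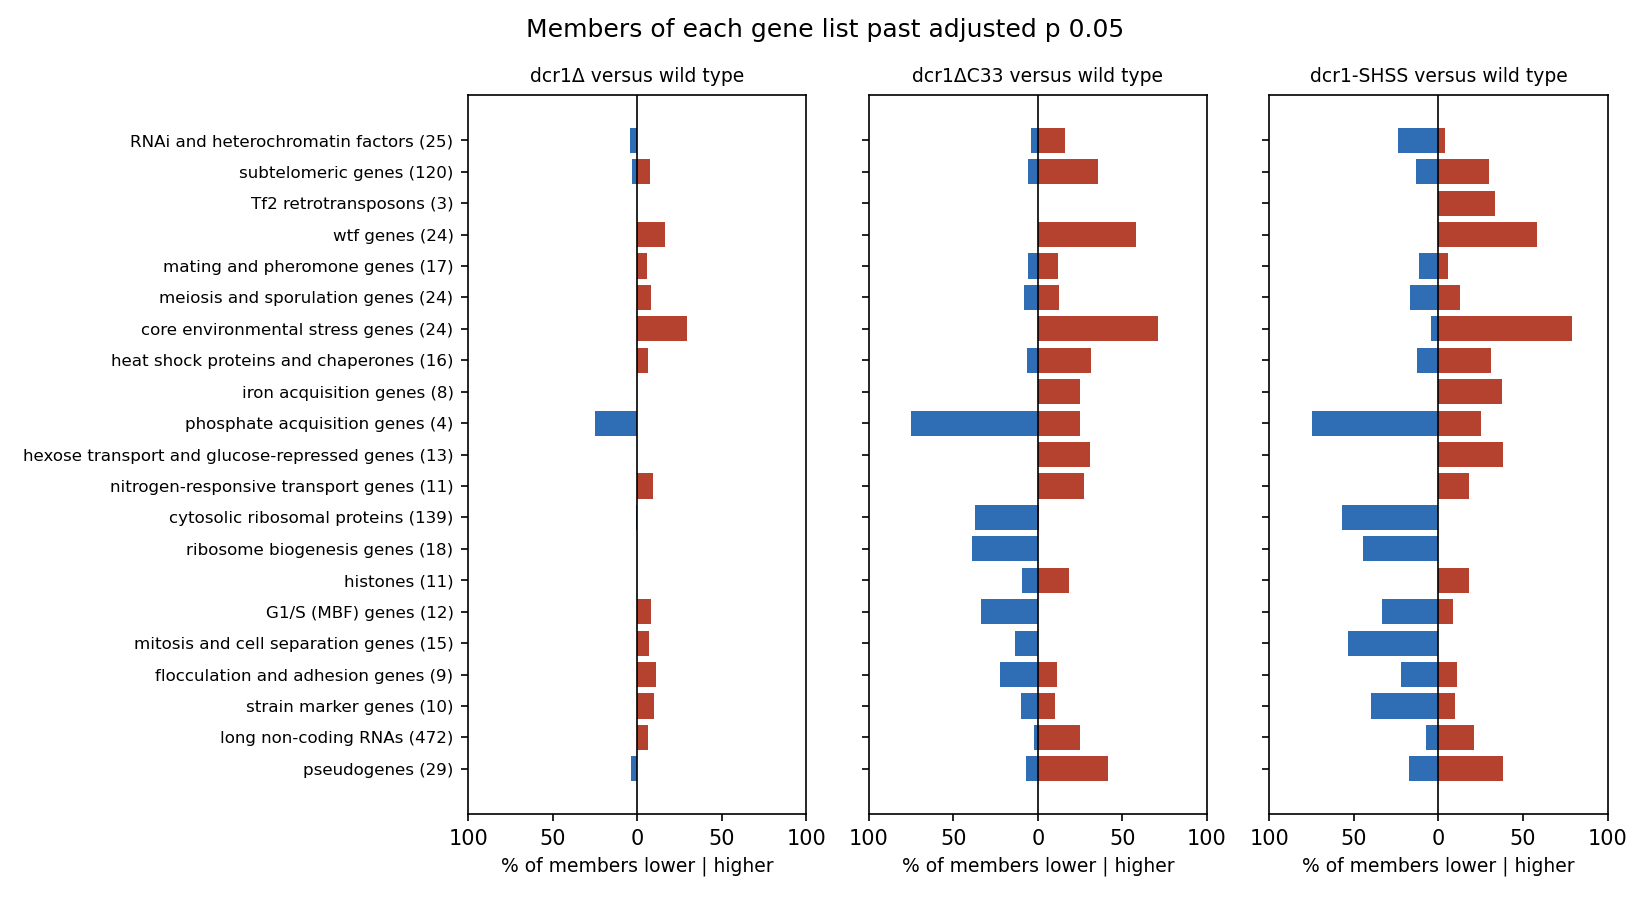
Percent of the measured members of each gene list (number of members in brackets) that lay lower (left, blue) or higher (right, red) past adjusted p = 0.05 in each mutant against wild type. In dcr1-SHSS 19 of 24 core environmental stress genes were higher and 79 of 139 cytosolic ribosomal protein genes were lower.

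The gene gaps that hold the 3 centromeres contained 13 measured non-coding RNAs, a group formed after the values were seen because no feature carried a centromeric name. SPNCRNA.231, SPNCRNA.232 and SPNCRNA.234 on chromosome I and SPNCRNA.373 on chromosome II rose in all 3 mutants. SPNCRNA.481 on chromosome III was called in dcr1Δ (adjusted p = 0.0238), but its levels of 4.75 in wild type and 5.54 in dcr1Δ are no higher than those taken as background at dcr1, so no size is given and no rise is claimed. SPNCRNA.231 rose by 2.25, 2.46 and 2.53 (± 0.11 each) in dcr1Δ, dcr1ΔC33 and dcr1-SHSS. The remaining members did not pass in any mutant against wild type. As a list the 13 gave unadjusted camera p = 2.09e-08, 0.00117 and 0.00775 in dcr1Δ, dcr1ΔC33 and dcr1-SHSS, and p = 0.00394, 0.0492 and 0.094 with an estimated correlation.

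The genes changed in the 3 mutants overlapped. Of the 154 features that rose in dcr1Δ, 143 also rose in dcr1ΔC33 and 141 in dcr1-SHSS, where independent lists of these sizes would share 22.7 and 23.1. Of the 18 that fell, 13 and 12 also fell, against 3.2 and 4.6 for independent lists. Between dcr1ΔC33 and dcr1-SHSS 637 rises and 785 falls were shared (121 and 248.3 for independent lists) and 1 feature went opposite ways. Opposite calls numbered 2 between dcr1Δ and dcr1ΔC33 and 3 between dcr1Δ and dcr1-SHSS. In all 3 mutants 141 features rose, among them SPNCRNA.234, ura4, cta3, frp2 and hsp16, and 12 fell, among them SPBPB10D8.03. The comparisons share the wild-type arrays, which are too few to split, so part of the excess may come from them. In 100 simulations of unchanged strains there were on average 0, 0 and 0.01 shared calls. Unchanged strains give almost no calls at all, so these simulations cannot show how much the shared arrays add to the overlap. Across genes, which are not independent replicates, the log2 changes of dcr1Δ correlated with those of dcr1ΔC33 at 0.773 (simulated 0.501; covariance 0.0571 against 0.005) and with those of dcr1-SHSS at 0.719 (simulated 0.503; covariance 0.0585 against 0.005), and those of dcr1ΔC33 and dcr1-SHSS at 0.927 (simulated 0.497; covariance 0.1109 against 0.0049). Without single arrays the sharing with dcr1Δ fell to 87 and 85 (without wild-type array 2), 73 and 73 (dcr1Δ array 2) and 82 and 81 (dcr1Δ array 3), from 156 and 153.

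**Figure D3:**
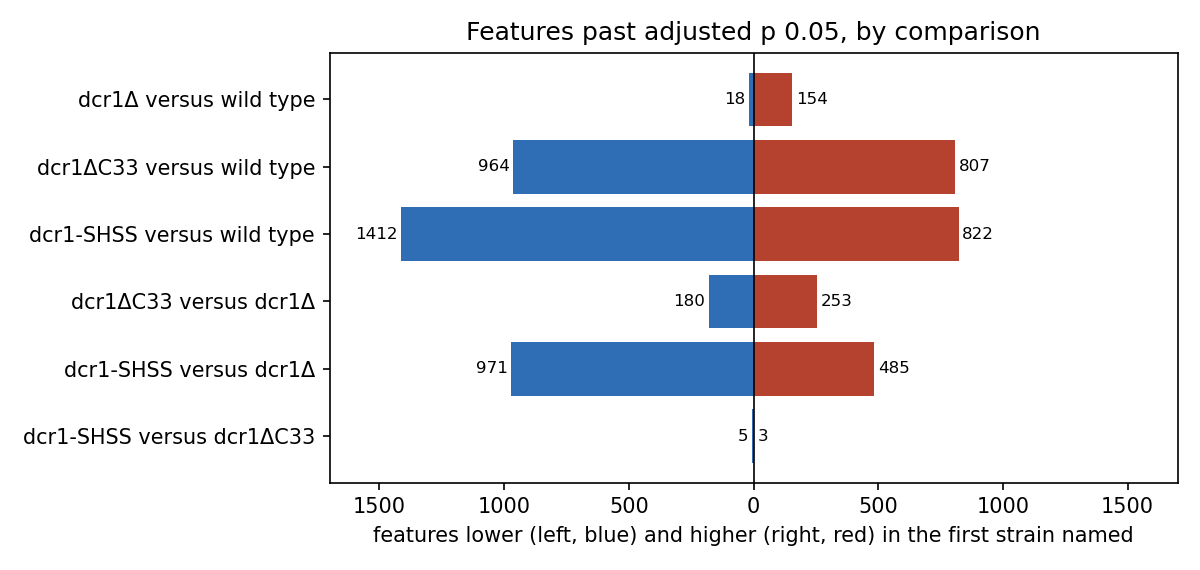
Number of features lower (left, blue) and higher (right, red) in the first strain named, past adjusted p = 0.05 of 5483 tested, for each of the 6 comparisons. The alleles dcr1ΔC33 and dcr1-SHSS differ from wild type at 1771 and 2234 features and from each other at 8.

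In dcr1ΔC33 against dcr1Δ, dcr1 itself was at least 39.5-fold higher, a lower bound set by background in dcr1Δ (log2 difference 5.30 ± 0.09 SE, n = 3 per group, adjusted p = 6.1e-11), gdt1 12.1-fold (3.59 ± 0.14) and ftm4 3.10-fold (1.63 ± 0.20), with urh1 (1.54 ± 0.11) and SPBC1773.03c (1.34 ± 0.11) next. SPAC8C9.04 was 5.11-fold lower (-2.35 ± 0.09, adjusted p = 1.98e-07), and pfl9 (-0.69 ± 0.16), pfl6 (-0.68 ± 0.15) and smp2 (-0.59 ± 0.15) were lower too. The size for smp2 is uncertain, because its level of 6.24 in dcr1ΔC33 is about that of background. SPNCRNA.481 was also called lower, from signal at the background level. In all, 433 features differed, 253 higher and 180 lower in dcr1ΔC33. The core environmental stress genes were higher as a list (10 of 24 past the threshold, camera adjusted p = 3.31e-11, and adjusted p = 0.343 with an estimated correlation), as were 21 subtelomeric genes with 4 lower (2.14e-05, and adjusted p = 0.518 with an estimated correlation). In the other direction, 7 of 139 ribosomal protein genes (2.32e-07), 3 of 15 mitosis and cell separation genes (0.00022), 5 of 12 G1/S genes (0.000442) and 3 of 18 ribosome biogenesis genes (0.0103) were lower. Heat shock genes (2 higher; 0.00685), long non-coding RNAs (21 higher, 6 lower; 0.00879), wtf genes (1 higher; 0.0122), glucose-repressed genes (none past; 0.0122) and pseudogenes (2 higher; 0.0445) shifted upward. Each of these lists lost its call with an estimated correlation (up to 0.518). The count was 847 (406 higher, 441 lower) with the replicate block and 272 with the arrays of these strains alone. It was 130 and 216 without dcr1Δ array 1 or 2, and 180, 235 and 120 without dcr1ΔC33 array 1, 2 or 3. The calls for pfl9, pfl6 and smp2 were each lost without some single arrays of either strain (adjusted p up to 0.0877, 0.0813 and 0.139).

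In dcr1-SHSS against dcr1Δ, dcr1 was at least 34.4-fold higher, again a lower bound (5.11 ± 0.09, n = 3 per group, adjusted p = 9.06e-11), gdt1 12.4-fold (3.63 ± 0.14), ftm4 3.91-fold (1.97 ± 0.20), cmt2 3.39-fold (1.76 ± 0.26) and SPAC750.01 3.16-fold (1.66 ± 0.21). The lowest were SPBCPT2R1.10 (-1.91 ± 0.51), SPAC977.03 (-1.33 ± 0.23), tlh1 (-1.27 ± 0.37) and SPNCRNA.287 (-1.26 ± 0.24). SPNCRNA.233 was also called lower, from signal at about the background level. In all, 1456 features differed, 485 higher and 971 lower in dcr1-SHSS. Of 139 ribosomal protein genes 51 were lower (camera adjusted p = 8.35e-07, and adjusted p = 0.518 with an estimated correlation) and of 24 core stress genes 16 were higher (7.18e-12, and adjusted p = 0.343 with an estimated correlation). Mitosis and cell separation genes (8 lower; 0.00227), G1/S genes (8 lower; 0.00685), ribosome biogenesis genes (7 lower; 0.00685) and strain markers (3 lower; 0.0493) shifted downward. Heat shock genes (5 higher, 1 lower; 0.00576), subtelomeric genes (25 higher, 21 lower; 0.0114) and hexose transport and glucose-repressed genes (4 higher; 0.0122) shifted upward, as did wtf genes (3 higher; 0.014), iron acquisition genes (2 higher; 0.0356) and histones (1 higher; 0.0358). These calls too were lost with an estimated correlation (up to 0.518). The count was 908 with the arrays of these strains alone, 750 and 937 without dcr1Δ array 1 or 2 and 968 without dcr1-SHSS array 2. The calls for SPBCPT2R1.10 (up to 0.0698 without dcr1Δ array 1 or 2), tlh1 (up to 0.101 without dcr1Δ array 1 or 2 or dcr1-SHSS array 2 or 3) and SPNCRNA.233 (up to 0.0967 without dcr1Δ array 2 or 3 or dcr1-SHSS array 1 or 2) were lost without single arrays.

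The alleles dcr1ΔC33 and dcr1-SHSS differed from each other at 8 features. SPAC8C9.04 was 4.95-fold higher in dcr1-SHSS than in dcr1ΔC33 (2.31 ± 0.09, n = 3 per group, adjusted p = 7.19e-07), ost4 1.70-fold (0.76 ± 0.12) and gon7 1.28-fold (0.35 ± 0.06). SPAC212.04c (-1.22 ± 0.15), the flap endonuclease gene rad2 (-0.34 ± 0.05) and mug62 (-0.28 ± 0.03) were lower. SPNCRNA.177 and prl4 were also called lower, from signal at about the background level, so no size is given for them. SPAC8C9.04 alone passed without each array in turn and at an adjusted p of 0.01. The others all lost their calls without dcr1ΔC33 array 1 or dcr1-SHSS array 2, at an adjusted p over single arrays of up to 0.117 (ost4), 0.179 (gon7), 0.0937 (SPAC212.04c), 0.113 (SPNCRNA.177), 0.142 (rad2), 0.121 (prl4) and 0.0681 (mug62). The count was 0 without the lowest 20 percent of features, SPAC8C9.04 among them, 1 with the arrays of these strains alone, 1 and 2 without dcr1ΔC33 array 1 or 3 and 3 and 1 without dcr1-SHSS array 1 or 2. At an unadjusted p under 0.05 there were 847 features, and the median absolute size of a called difference was 0.45. As lists, core environmental stress genes (camera adjusted p = 0.00133) and iron acquisition genes (0.0293) lay higher in dcr1-SHSS with no member past the threshold, and long non-coding RNAs lower with 2 members past it (0.0293). Each of these had adjusted p = 0.518 with an estimated correlation.

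The sizes of the changes were compared at the 235 features that moved at least 1.5-fold in dcr1ΔC33. The log2 change in dcr1Δ had a median of 0.473 times that in dcr1ΔC33 (quartiles 0.396 and 0.561), and 230 had the same sign. The log2 change in dcr1-SHSS had a median of 1.048 times that in dcr1ΔC33 (quartiles 0.933 and 1.166). The centromere-gap RNAs were an exception, with a median ratio of 0.979 over SPNCRNA.231, SPNCRNA.232, SPNCRNA.234 and SPNCRNA.373, and ura4, whose genotype in these strains is not given, had a ratio of 1.10. The changes of SPNCRNA.232 are lower bounds in both strains, so its own ratio is uncertain.

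**Figure D4:**
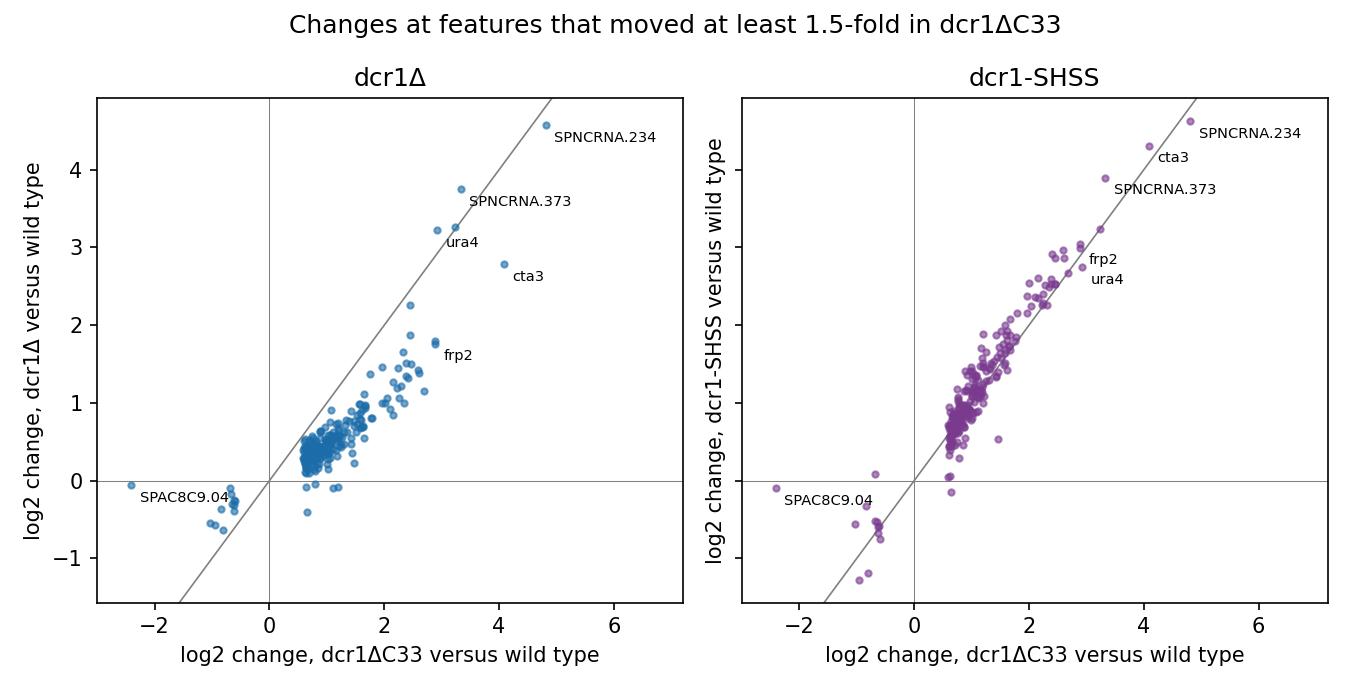
Log2 change against wild type in dcr1Δ (left) and dcr1-SHSS (right, vertical axes) plotted over the log2 change in dcr1ΔC33 (horizontal axes) for 235 features that moved at least 1.5-fold in dcr1ΔC33; each point is a feature and the diagonal marks equal changes. The dcr1Δ points lie below the diagonal for most rises (median ratio 0.473), with SPNCRNA.234 near it and SPNCRNA.373 and ura4 above it, and the dcr1-SHSS points lie along it (1.048).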

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

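The tests of array scale, picked features and signal level were set before their results were seen; those of neighbouring genes, single arrays and culture state were chosen after. Tests of the difference between mutants marked 433 features in dcr1ΔC33 versus dcr1Δ, 1456 in dcr1-SHSS versus dcr1Δ and 8 in dcr1-SHSS versus dcr1ΔC33. Differences of at least 4-fold between mutants occurred at dcr1, which was above the background level of dcr1Δ by at least 5.30 in dcr1ΔC33 and 5.11 in dcr1-SHSS (log2), at gdt1, above dcr1Δ by 3.59 and 3.63, and at SPAC8C9.04, at -2.35 in dcr1ΔC33 versus dcr1Δ and 2.31 in dcr1-SHSS versus dcr1ΔC33.

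The 6 arrays of a comparison can be split in 10 ways, too few for a share under 0.05. In every split but the real split, each group holds arrays of both strains. A difference between the strains then partly cancels and widens the spread within groups. Low gene counts in those splits follow by construction, so they are no null for the gene calls and no conclusion is drawn from them. In each comparison only 1 split, the real one, gave as many genes: the real counts were 172, 1771, 2234, 433, 1456 and 8, and the highest among the other splits were 1, 0, 0, 0, 1 and 0, in the order dcr1Δ, dcr1ΔC33 and dcr1-SHSS versus wild type, dcr1ΔC33 and dcr1-SHSS versus dcr1Δ, and dcr1-SHSS versus dcr1ΔC33. For gene lists, adjusted within each comparison, splits with as many list calls numbered 3 of 10 in dcr1Δ (9 calls, highest other 11), 2 of 10 in dcr1ΔC33 (9, highest other 9) and 3 of 10 in dcr1-SHSS (10, highest other 11). The other splits mix arrays whose replicate numbers pair in dcr1Δ and dcr1ΔC33 versus wild type, so their list calls may hold the replicate effect and are no clean null. For dcr1-SHSS versus wild type the numbers were not treated as pairing, but pairs 2 and 3 correlated at 0.284 and 0.266. A replicate effect is therefore not excluded there either. The list calls also rest on the preset correlation of 0.01, where estimates ran from -0.034 (histones) to 0.522 (iron acquisition genes). The splits were not run with estimated correlations, so the source of their list calls was not settled. In none of these comparisons did the real split give more list calls than every other split.

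Most changes were smaller in dcr1Δ, the full deletion, than in dcr1ΔC33 at the same features (median ratio 0.473), although centromere-gap RNAs and ura4 changed about equally. Picking features by their change in dcr1ΔC33 would favour this, but among 61 features picked by their change in dcr1Δ instead the median ratio was 0.589 with an upper quartile of 0.713, below 1. Array scale is argued against by quantile normalization, after which the ratio was 0.423. The stress or growth state of the cultures stays open: the core environmental stress genes averaged 0.32 higher in dcr1ΔC33 than in dcr1Δ against a pooled SD of 0.07 between arrays, and state and genotype cannot be told apart because each strain was grown as its own cultures. A stronger effect of dcr1ΔC33 and dcr1-SHSS than of the deletion, or a difference that arose in the dcr1Δ strain, also remains open and was not tested.

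The transcript gdt1 was low in dcr1Δ and SPAC8C9.04 was low in dcr1ΔC33. A single aberrant array is argued against for both, since the highest dcr1Δ array lay -3.48 from the lowest wild-type array at gdt1, and the highest dcr1ΔC33 array -2.16 at SPAC8C9.04. Loss of the surrounding chromosome segment is argued against for SPAC8C9.04, whose nearest measured neighbours cgs1 and dtd1 differed by 0.20 and 0.33. For gdt1 it cannot be told apart, because its neighbours are dim: SPAC186.04c fell by 0.97, SPAC186.06 differed by -0.40 (adjusted p = 0.272) and SPAC186.02c, further off, rose by 1.80. A change confined to each gene in that strain, unrelated to dcr1, remains open, and no biological explanation was tested.

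Ribosomal protein genes were lower in dcr1-SHSS, with a median log2 change of -0.14 over 139 genes, of which 79 fell and 60 did not pass; the list call was lost at adjusted p = 0.53 with an estimated correlation. A trend of change with signal level is argued against: among 1000 lists of other features matched on level the lowest median was -0.058. Array scale is argued against as the whole cause, since 76 genes fell after quantile normalization and 63 after median centring, beside 79. Genotype and culture state stay open, as above, and were not tested here.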

How the results depend on the processing

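Array number and background in dim features set the limits here, and the alternatives were planned except the outermost genes. The number of genes changed in dcr1Δ versus wild type was 172; it became 73 with the arrays of 2 strains only, 295 with the replicate block, 62 at 1.5-fold and 68 at adjusted p 0.01, and 82 to 168 without single arrays. In dcr1ΔC33 versus wild type (1771) it became 2267 with the block, 235 and 852 at these thresholds and 1178 to 1483 without single arrays; in dcr1-SHSS versus wild type (2234), 269 and 1217, and 1729 to 2001. In dcr1ΔC33 versus dcr1Δ (433) it became 272 with 2 strains only, 847 with the block, 77 and 90 at the thresholds and 120 to 434 without single arrays; in dcr1-SHSS versus dcr1Δ (1456), 908 with 2 strains only, 1938 with the block, 146 and 499 at the thresholds and 750 to 1409 without single arrays. In dcr1-SHSS versus dcr1ΔC33 (8) it became 2 after quantile normalization, 0 without the lowest 20 percent of features, 1 with 2 strains only and 4 with trend and robust moderation. There it was also 3 at 1.5-fold, 1 at adjusted p 0.01 and 1 to 7 without single arrays. The block gave 8 there and 2653 in dcr1-SHSS versus wild type, comparisons in which the first same-numbered pair fell short of 0.1. The stricter thresholds and fewer arrays or residual degrees of freedom lower counts by construction; other causes were not tested.

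The share of higher calls moved by over 10 points with scaling in dcr1Δ versus wild type (154 higher and 18 lower; 100 and 28 after quantile normalization), in dcr1-SHSS versus dcr1Δ (485 and 971; 536 and 666 after median centring) and in dcr1-SHSS versus dcr1ΔC33 (3 and 5; 1 and 1 after quantile normalization). The overlap of genes changed between mutants: dcr1Δ versus wild type and dcr1ΔC33 versus wild type (156 in the same direction) became 66 with 2 strains only and 268 with the block, and 73 to 156 without single arrays. The overlap of genes changed between mutants: dcr1Δ versus wild type and dcr1-SHSS versus wild type (153) became 64, 256 and 73 to 149, and that of dcr1ΔC33 and dcr1-SHSS (1422) became 1029 to 1283 without single arrays.

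The dcr1 change stayed at -5.11 to -4.89 in dcr1Δ without single arrays; in dcr1ΔC33 it was 0.28 to 0.34, with the call lost at 0.28 (without wild-type array 1) and 0.30 (without dcr1ΔC33 array 2); in dcr1-SHSS it was 0.08 to 0.14. List calls (28) became 0 with an estimated correlation, 55 with fry's mixed test, and 23 to 29 without single arrays. The ribosomal protein list in dcr1Δ turned from lower to higher without passing after quantile normalization (median -0.001, adjusted p = 0.737), and the strain markers in dcr1ΔC33 from lower to higher with fry (median -0.065, adjusted p = 0.0379); the cause was not tested. Of 885 alternatives over 63 list results 794 kept direction and side of the threshold, 62 lost a call, 27 gained one and 2 reversed; of 2489 over 212 named-gene results these were 2261, 223, 5 and 0. With the block, where numbers pair the arrays, rpl1602 lost its call in dcr1Δ (adjusted p = 0.0515), imp3 in dcr1Δ versus wild type gained one (0.0224) and the mitosis list gained one in dcr1ΔC33 (0.0451); it changed no other call there.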

Other observations

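Families of symbols were compared after the data had been seen, 54 families in 162 tests, of which 37 passed with camera and 0 with an estimated correlation. In dcr1-SHSS versus wild type 15 of 21 trm genes, which modify transfer RNA, were lower and none higher (median log2 change -0.24, camera adjusted p = 0.000552, and adjusted p = 0.618 with an estimated correlation), with trm5 at -0.39 ± 0.06. Of 26 tif genes, which encode translation initiation factors, 16 were lower and none higher (0.00596, and adjusted p = 0.753 with an estimated correlation), and of 10 ade genes of purine synthesis 7 were lower (0.0204, and adjusted p = 0.618 with an estimated correlation). Of 28 atg genes of autophagy 11 were higher and 1 lower (6.44e-05, and adjusted p = 0.495 with an estimated correlation), with atg2402 at 0.83 ± 0.08. Of 12 hsp genes 8 were higher and none lower (median 0.72, 6.44e-05, and adjusted p = 0.419 with an estimated correlation). In dcr1ΔC33 8 of 21 trm and 15 of 26 tif genes were lower and 10 of 28 atg genes were higher, and 8 of 12 hsp genes were higher (0.000316, and adjusted p = 0.419 with an estimated correlation), while the planned heat shock and chaperone list did not pass there.

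The septin gene spn6, which adjoins dcr1 in the reference order and was picked after its values were seen, rose by 0.70 ± 0.10 in dcr1Δ, 1.46 ± 0.10 in dcr1ΔC33 and 1.40 ± 0.10 in dcr1-SHSS (adjusted p = 0.00274, 3.52e-06 and 4.56e-06). The array target does not separate strands. The marker gene ura4 lay at log2 levels of 7.76, 7.36 and 7.79 in wild type, 10.93, 10.80 and 10.85 in dcr1Δ, 10.60, 10.47 and 10.62 in dcr1ΔC33 and 10.44, 10.34 and 10.39 in dcr1-SHSS.

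The 160 outermost measured protein-coding genes of chromosomes I and II, chosen after seeing the data, included 12 higher and 6 lower in dcr1Δ, 46 and 21 in dcr1ΔC33 and 44 and 30 in dcr1-SHSS (unadjusted camera p = 0.0325, 6.28e-05 and 0.00195; p = 0.369, 0.113 and 0.205 with an estimated correlation).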
